A study of Mus musculus with 2 samples.

How the data were processed

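Alveolar macrophages were sorted by flow cytometry from lungs of mice aged 8 to 10 weeks and lysed in Trizol, and biotinylated cRNA was made from 6 ug of total RNA, per the labels' protocols. Each genotype, Lysm-Cre control and Lysm-Cre Ssu72fl/fl, had 1 Affymetrix gene-level array; groups were taken from the genotype label. How many mice contributed to an array is not given in the sources used here.

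The deposited values are log2 expression values made by the authors, 1 per transcript cluster, called a feature here. That they are on a log2 scale was inferred from their range, 4.23 to 13.5. The submitters' processing notes name MAS5, without its role; the background correction, normalization, offset and centring are not given in the sources used here. The deposited column medians were 4.65 (control) and 4.66 (Ssu72fl/fl), and the 95th percentiles 6.14 and 5.94. The direction of each difference follows from the genotype labels of the columns. A scale compressed by an offset would make every difference smaller than the true fold change, above all at low signal, where most features lie: 5.27% had a mean level over 6. Scanner files were not used here.

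Features were named from the platform annotation. Of 33793 features, 23521 carried 1 gene symbol, 1814 several and 8458 none. Only those with 1 were used for genes. Of these, 23328 were matched through the Entrez identifier to a RefSeq gene table of assembly GRCm38.p6 and took its symbol. The genome build of the array is not given in the sources used here, so no coordinates are printed. As a look at the naming, the mean levels of some macrophage genes were placed among those of named genes: Lyz2, Chil3, Ctsd, Plet1 and Cd9 lay above the 99th percentile, Marco at 96.3 and Siglecf at 82.3. The surfactant gene Sftpc, of alveolar type 2 cells, was at 99.7.

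The floor was the 50th percentile of all values on both arrays, 4.65. Control features could not be told from other unnamed features, so all features entered it. Values below the floor were set to it, a gene was compared if at least 1 array was above it, and each gene took its probe set with the highest mean. This left 13015 of 22180 genes, of which 2081 were below the floor on 1 array and have only a lower bound. With 1 array per genotype, no test between genotypes was possible: genes were counted at a 2-fold difference, and the spread at a level is the robust SD (scaled median absolute deviation) of differences among genes in the same of 20 bins of mean signal. It describes scatter between genes, measurement error included, and not scatter between animals.

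For each of 50 gene lists, the median difference of the compared members was placed among the medians of 10000 random lists of the same size, drawn from the same 20 bins. Below the 2.5th or above the 97.5th percentile counted as below or above the range, and at least 5 compared members were required. The percentile describes these 2 arrays and is no p-value. The highest bin runs from a mean level of 6.18 to 13.1, so matching is coarse for highly expressed lists. The spread of 0.33 given for its genes is that of deposited differences over all those levels.

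The lists, thresholds, most alternatives and the rule for named genes were set before the data were examined. The rule took Ssu72, the 12 highest and 12 lowest differences among genes above the floor on both arrays, the 6 largest bounds each way, up to 2 members at each end of each list described, and Csf2ra, Csf2rb, Csf2rb2, Pparg, Siglecf, Itgax and Lyz2. It left out predicted and clone-named genes and genes with a discordant probe set; Gm11983 and Gm5451, which it leaves out, were named after their values were seen because the 2-fold counts include them. Other sets chosen after the values were seen are marked as such where they appear.

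Alternatives were median centring, quantile normalization, removal of a loess trend of difference on level (span 0.3), floors at the 25th and 75th percentiles, the mean of a gene's probe sets, thresholds of 1.5-fold and 3-fold, and random lists without matching. The loess over all features was the one intended. It was dominated by the many dim features and left a median of 0.48 in features above level 10. After its residuals and its list calls had been seen, the trend was refitted by lowess on medians of narrow level bins of at least 10 features, which left -0.0066 there. The level-adjusted values in the text come from this refit. The refit changed 2 list calls: MHC class II presentation went from percentile 5.0 (inside) to 1.91 (below), and chemokines from 1.49 (below) to 7.85 (inside). Both fits put 9 lists below the range, 8 of them in common, and results with each are reported as separate alternatives.

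The procedure was tested on simulated arrays with the scatter of the real ones for the comparison of Ssu72fl/fl with control, over 12712 genes. Of 200 genes changed by 1.5 on the log2 scale, 90.0% passed the 2-fold threshold (98 of 100 higher and 82 of 100 lower). Of 12238 unchanged genes, 0 passed it. That 0 holds for the simulated scatter alone. It gives no rate of false calls among the real 2-fold genes, which have no replicate arrays. The 82 of 100 gives no rate of recovery for dim genes either. A gene less than 1 above the floor on the control array cannot read 2-fold lower, because values below the floor were set to it. All 12 lists of 25 genes shifted by 0.15 and 3 of 100 unchanged lists fell outside the range. These counts also hold for the simulated lists alone. Smaller shifts were not simulated, such as the level-adjusted median of -0.092 of the scavenger receptor list. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures matplotlib 3.10.9.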

Results

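Gene expression was measured in alveolar macrophages, the resident macrophages of the lung air spaces, sorted by flow cytometry from the lungs of mice aged 8 to 10 weeks. The series held 2 Affymetrix gene-level arrays, 1 from Lysm-Cre control mice and 1 from mice labelled Lysm-Cre Ssu72fl/fl. In Lysm-Cre mice, Cre recombinase is expressed from the lysozyme 2 locus in myeloid cells, and fl/fl marks an allele flanked by recombination sites. Ssu72 encodes a phosphatase of the C-terminal domain of RNA polymerase II. The comparison therefore asked how the transcriptome of alveolar macrophages differed where myeloid cells carried the floxed Ssu72 allele together with Cre. With 1 array per genotype there was no replicate check, so no p-value or standard deviation between animals is given, and the number of arrays limits the precision of each value. All differences are log2 values of the array labelled Ssu72fl/fl minus the control array, and "higher" and "lower" refer to that array. As the only error that could be attached to a gene, the text gives the robust SD of the differences among genes of similar signal, here called the spread at that level.

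The targeted gene was not lower on the array labelled Ssu72fl/fl. Its single probe set read 4.862 on the control array and 4.998 on the array labelled Ssu72fl/fl, a difference of 0.14 against a spread at that level of 0.14. The control signal lay 0.21 above the floor of 4.65, and its mean level was at the 72.0th percentile of named genes. The positions of its probes relative to the deleted part of the gene are not given in the sources used here. The value therefore did not check the label, and directions below rest on the label alone. Of 24 compared genes next to Ssu72 on its chromosome, 16 were lower and 8 higher, with a median of -0.043 that lay inside the range of random gene lists (percentile 11.99). Their ends were Gnb1 (-0.30, level-adjusted -0.060) and Cdk11b (-0.15), and Cptp (0.20) and Tmem52 (0.18).

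The difference between the arrays varied with the signal level, although single features also scattered widely around each median. Medians over all 33793 features were 4.65 on the control array and 4.66 on the array labelled Ssu72fl/fl, but the 99th percentiles were 8.05 and 7.66. The median difference was 0.0080 for features with a mean level from 4 to 5 and -0.037 from 5 to 6. It was -0.28 from 6 to 7 (robust SD between features 0.41), -0.44 from 7 to 8, -0.47 from 8 to 9 and -0.38 from 9 to 10, and -0.13 over the 76 features above 10. Between 6 and 10, 79.1% of 1705 features were lower. Highly expressed macrophage genes shared this offset: Lyz2, the lysozyme gene that carries Cre in this design, was at 10.23 and 9.74 (-0.49). Because of this trend, a level-adjusted difference is given beside the deposited one where it matters. It is the difference left after a smooth curve of difference on level was removed, with a curve whose form was chosen after the data were seen. The curve was fitted on all features. At levels 6 to 10 their median was -0.34, against -0.27 for 665 protein-coding genes. Level-adjusted values of protein-coding genes there can therefore lie somewhat high.

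**Figure D1:**
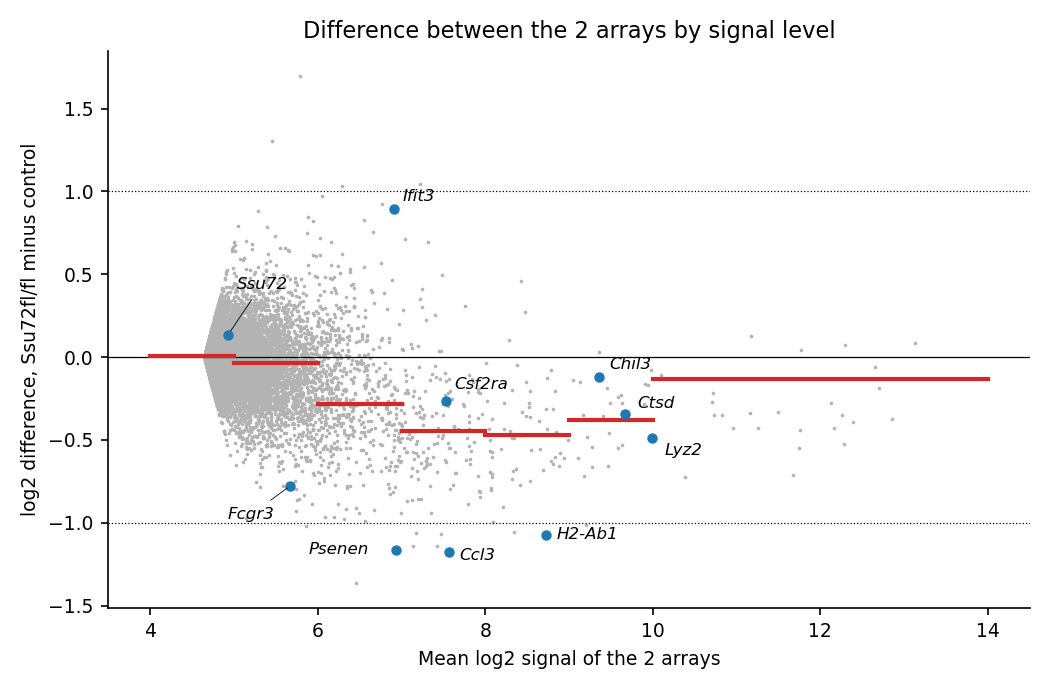
Difference between the arrays (log2, array labelled Ssu72fl/fl minus control) against mean log2 signal for the 13015 compared genes (grey points), with named genes in blue. Red bars are medians over all features in each range of level, which run from 0.0080 between 4 and 5 to -0.47 between 8 and 9; dotted lines mark 2-fold differences.

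Few genes differed by 2-fold or more, and they were mostly non-coding RNAs, pseudogenes and members of multigene families. Of 13015 compared genes, 11 were at least 2-fold lower and 4 at least 2-fold higher, so 26.7% of these genes were higher. The floor of 4.65 limited both counts. A 2-fold lower gene had to lie at least 1 above it on the control array. A 2-fold higher gene had to do so on the array labelled Ssu72fl/fl. Most compared genes had too little signal on the control array to count as lower. The split turned with the scaling: after quantile normalization 13 were higher and 1 lower (92.9% higher), and with the trend removed by loess 11 were higher and 1 lower (91.7% higher). The protein-coding genes among the lower ones were Ccl3 (-1.17), a chemokine that attracts leukocytes, Psenen (-1.16), a gamma-secretase subunit, H2-Ab1 (-1.07), the beta chain of the MHC class II molecule I-A, and the vomeronasal receptor gene Vmn1r129 (-1.02). Ccl3 was at 8.15 and 6.98, and H2-Ab1 at 9.26 and 8.19, both in the highest bin of signal, whose spread was 0.33. The others were the immunoglobulin segment Igkv5-43 (-1.36), Astx5 (-1.14), Mir101c (-1.14), the small nucleolar RNAs Snord11 (-1.07) and Snora31 (-1.05), the pseudogene Gm5451 (-1.06) and Rnu3a (-1.01). Snord73b (-0.99) and Mir2137 (-0.99) completed the 12 lowest genes of the naming rule. When level-adjusted, only Igkv5-43 (-1.07) was still at least 2-fold lower. Snord11 became -0.62, Snora31 -0.59, Gm5451 -0.61, Rnu3a -0.63 and Snord73b -0.52.

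The 4 genes at least 2-fold higher were the pseudogene Gm11983 (1.70), the microRNA genes Mir3083 (1.30) and Mir483 (1.04), and the vomeronasal receptor gene Vmn2r55 (1.03). Ifit3, an interferon-induced antiviral gene, was at 6.47 and 7.36 (0.89, or 1.31 when level-adjusted). It was followed by Fthl17b (0.83), Ptms (0.76), Zfp747 (0.75), Med25 (0.73), a Mediator subunit, and the type I interferon gene Ifna15 (0.72). Mir1943 (0.97), Mir339 (0.92) and the pseudogene Gpx2-ps1 (0.88) were also among the 12 highest. Of genes below the floor on 1 array, the differences are lower bounds. The largest were at least 0.79 for Frg2f8, 0.70 for Olfr772, 0.65 for Btbd35f28, 0.53 for Olfr1128, 0.51 for Sult2a5 and 0.50 for Olfr1029 on the higher side. On the lower side they were Olfr1474 (-0.97), Olfr875 (-0.50), Fundc2 (-0.44), Vsnl1 (-0.40), Bccip (-0.35) and Brat1 (-0.34). Among genes 2-fold different, 2 had a further compared probe set, and both went the same way in all of them (exact 95% interval 15.8 to 100%). Over 438 genes with 2 compared probe sets, the differences of the pair correlated weakly (across genes, which are not independent replicates: Pearson r = 0.219, Spearman rho = 0.0575), with an SD between them of 0.191.

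Alveolar macrophage identity genes were lower on the deposited scale, with a median inside the random range for their signal. Of 29 compared genes 27 were lower and 2 higher, with a median of -0.25, against -0.14 for random lists of matched signal. That is percentile 5.52, inside the central 95%. Olr1 (-0.60, level-adjusted -0.14), the oxidised LDL receptor, and Atp6v0d2 (-0.55, level-adjusted -0.11), a proton pump subunit, were lowest, and Trim29 (0.27, level-adjusted 0.41) and the fatty acid binding protein gene Fabp4 (0.19) highest. Pparg, a transcription factor needed for alveolar macrophage development, was at 6.04 and 5.65 (-0.39), Itgax (CD11c) at 7.31 and 6.82 (-0.49) and Siglecf at 5.18 and 5.09 (-0.088). When level-adjusted these became -0.25, -0.045 and -0.065, each smaller than the spread at its level (0.26, 0.33 and 0.16), and the list median became -0.025 (percentile 17.9).

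Genes of the GM-CSF receptor and its signalling, on which alveolar macrophages depend, showed no common shift. Of 30 compared, 19 were lower and 11 higher, with a median of -0.052 at percentile 49.4 (level-adjusted 0.020, 17 of 30 higher). The receptor subunits were at 7.66 and 7.39 for Csf2ra (-0.27), 5.42 and 5.28 for Csf2rb (-0.14) and 5.61 and 5.57 for Csf2rb2 (-0.034). The direction of Csf2ra depended on the scaling: its level-adjusted difference was 0.19, against a spread of 0.33. The kinase gene Pim2 (0.61) and the cytokine gene Osm (0.30, level-adjusted 0.59) were highest, and the survival gene Mcl1 (-0.54) and the phosphatase gene Ptpn6 (-0.49) lowest. The lower 2 became -0.13 and -0.18 when level-adjusted, inside a spread of 0.33. TGF-beta signalling genes had a median of -0.047 (percentile 27.0; 20 of 28 lower), from Skil (-0.54) and Bmpr2 (-0.46) to Bambi (0.40) and Itgb8 (at least 0.13).

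The list of genes shared by macrophages in general had a lower median than random lists of its level. Of 29 core macrophage genes 27 were lower, with a median of -0.38 (percentile 0.175; level-adjusted -0.12, percentile 0.41). The Fc receptor gene Fcgr3 was at 6.06 and 5.29 (-0.78, level-adjusted -0.67 against a spread of 0.23). The protease gene Ctss was at 8.69 and 7.95 (-0.74, level-adjusted -0.28). That lay inside the spread of 0.33 of its wide bin, but not inside the robust SD of 0.25 of features at levels 8 to 9. Maf (0.24) and Trem2 (0.20) were the only members higher. Of 30 scavenger and phagocytic receptor genes 27 were lower, with a median of -0.19, below all 10000 random lists on the deposited scale (level-adjusted -0.092, percentile 0.15). Mertk (-0.51), a receptor for apoptotic cells, followed Fcgr3 at the lower end, but its level-adjusted difference was -0.16 against a spread of 0.33; Clec4e (0.18) and Scara5 (0.049) were highest. Of 14 MHC class II presentation genes 12 were lower, with a median of -0.32 (percentile 0.25). H2-Ab1 (-1.07, level-adjusted -0.63) and the endosomal protease gene Lgmn (-0.91, level-adjusted -0.61) were lowest, and Ciita (0.17), the master activator of class II genes, and Cd40 (0.042) highest. The class II call depended on how the trend was removed: its level-adjusted percentile was 1.91, but 5.0, inside the range, with the loess specified before the data were examined. On the deposited scale, of 34 lysosome genes 26 were lower, with a median of -0.28 (percentile 0.17), from Lipa (-0.79) and Ctss (-0.74) to Smpd1 (0.42) and Ctsf (0.16). The level-adjusted lysosome median was -0.022 (percentile 18.3, inside the range).

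**Figure D2:**
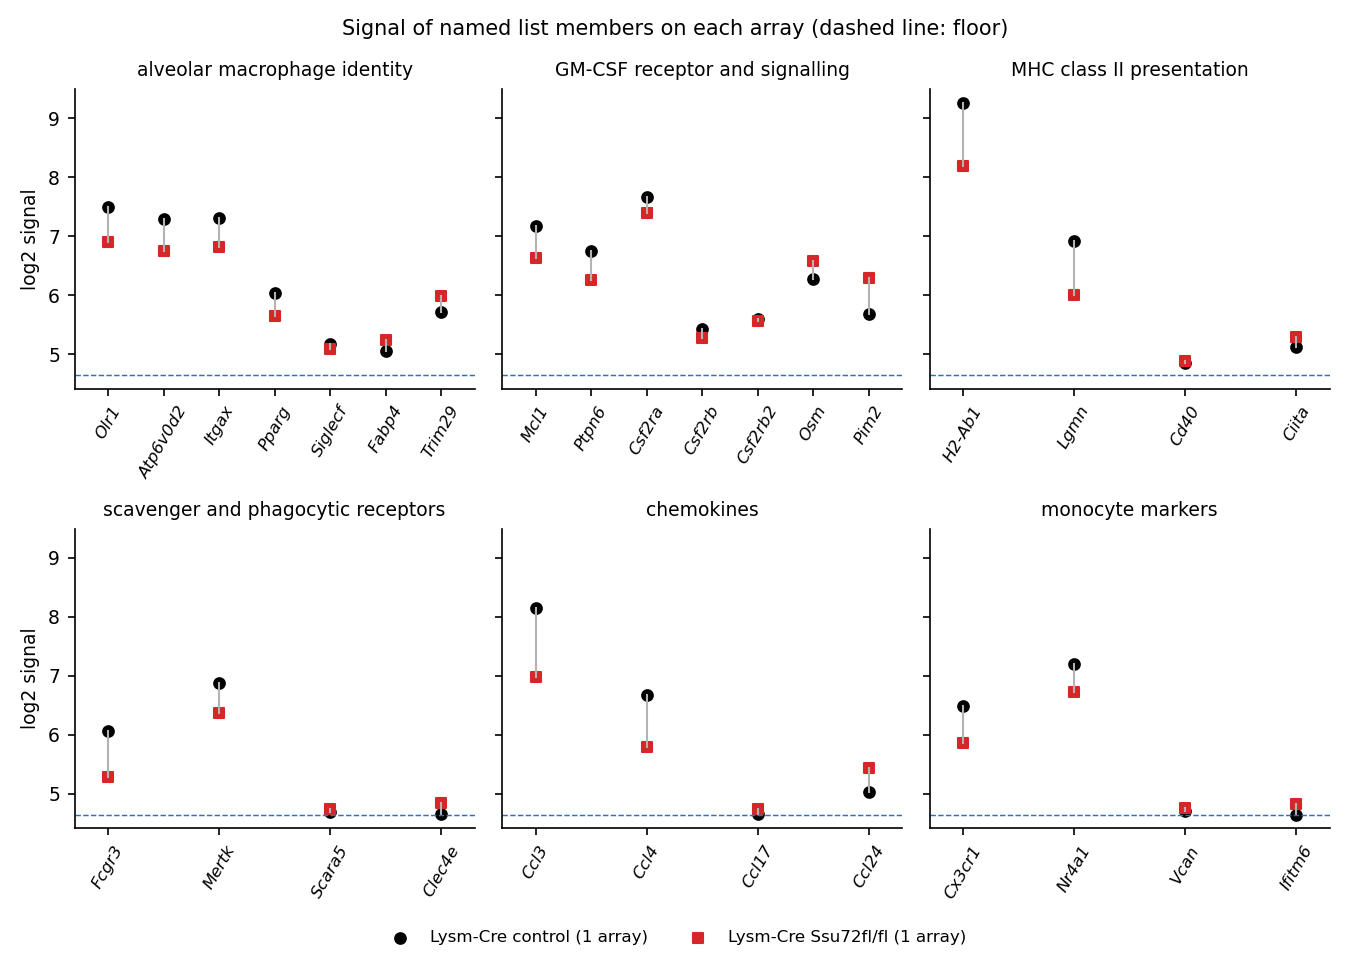
Log2 signal of named members of 6 gene lists on the control array (black circles) and the array labelled Ssu72fl/fl (red squares), 1 array each, with the floor of 4.65 as a dashed line and a grey line joining the values of 1 gene. H2-Ab1 is at 9.26 and 8.19 and Ccl3 at 8.15 and 6.98, whereas Csf2rb2 is at 5.61 and 5.57.

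The marker lists of interstitial macrophages and monocytes were also lower. Of 20 compared interstitial macrophage markers 18 were lower, with a median of -0.28 (percentile 0.010; level-adjusted -0.13, percentile 0.30). This list shares its lowest members, H2-Ab1 (-1.07) and H2-Aa (-0.86, level-adjusted -0.40), with the class II list; Maf (0.24) and Folr2 (0.12) were highest. Of 19 monocyte markers 15 were lower, with a median of -0.18 (percentile 0.070; level-adjusted -0.11, percentile 0.23), from the chemokine receptor gene Cx3cr1 (-0.63, level-adjusted -0.42) and Nr4a1 (-0.48) to Ifitm6 (at least 0.17) and Vcan (0.057). Nr4a1 showed almost no difference when level-adjusted (-0.056 against a spread of 0.33). The core macrophage, scavenger receptor, interstitial macrophage and monocyte lists, pooled after their calls in all settings had been seen, held 82 different compared genes, 15 of them in more than 1 list, of which 72 were lower on the deposited scale (median -0.29) and 62 when level-adjusted (median -0.11). Dendritic cell markers (median -0.036, 12 of 15 lower, percentile 31.5) and neutrophil markers (-0.032, 9 of 15 lower, percentile 22.4) lay inside the random range. When level-adjusted, the median of dendritic cell markers was -0.0076, with 9 of 15 lower. With the floor at the 75th percentile, which left 8 dendritic cell markers, their median was -0.35 and lay below the range (percentile 1.06). The dendritic and neutrophil lists had as lowest members Ccl22 (-0.51) and Cd207 (-0.45), and Cxcr4 (-0.66, level-adjusted -0.25) and Il1r2 (-0.52), and as highest Cd24a (0.17) and Kit (at least 0.081), and Mmp9 (0.12) and Lcn2 (0.11).

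Markers of lymphoid, granulocytic and structural cells mostly stayed inside the random range. T cell markers had a median of 0.050 (11 of 14 higher, percentile 92.0), from Lat (0.68) and Foxp3 (0.33) to Ccr7 (-0.099, level-adjusted -0.032) and Cd5 (-0.039). With the floor at the 75th percentile, 6 of them were compared and lay above the range (median 0.14, percentile 98.5). All 9 compared markers of eosinophils, mast cells and basophils were higher by small amounts (median 0.074, percentile 94.8), from Epx (0.17) and Il13 (0.13) to Prss34 (0.0081) and Gata1 (0.0018). Of 15 B and plasma cell markers 8 were higher and 7 lower, with Blk (0.22) highest. The lowest was the immunoglobulin gene Ighm, at 7.46 and 6.88 (-0.58, level-adjusted -0.13 against a spread of 0.33). Medians were 0.00080 for B and plasma cell markers (percentile 51.7; level-adjusted -0.0029), 0.012 for NK and innate lymphoid markers (60.5), -0.012 for alveolar type 1, club and ciliated cell markers (46.3; level-adjusted 0.0056), -0.053 for endothelial markers (14.4) and -0.034 for fibroblast, smooth muscle and mesothelial markers (33.0). Alveolar epithelial type 2 markers lay below the range (median -0.11, 18 of 21 lower, percentile 2.21; level-adjusted -0.083, percentile 1.73). That call was lost with median centring (percentile 2.74) and with the floor at the 25th (2.70) or 75th percentile (11.1). The surfactant gene Sftpc read 8.71 and 8.35 (-0.36, level-adjusted 0.090), next to Scd1 (-0.51) at the lower end, with Etv5 (0.15) and Lamp3 (0.059) highest. The 5 compared erythroid and platelet markers also lay below it (median -0.18, percentile 2.10), from Treml1 (-0.26) and Gp9 (-0.25, level-adjusted -0.17) to Itga2b (0.029) and Slc4a1 (0.012). With the floor at the 25th percentile, 10 of these markers were compared and the median was -0.017 (percentile 25.6, inside the range).

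The 6 lists of inflammatory, interferon, MHC class I, alternative activation and immediate early genes had medians below 0 and inside the random range on the deposited scale. Of 21 chemokine genes 16 were lower, with a median of -0.13 at percentile 2.70, just inside the range (level-adjusted percentile 7.85). The list lay below the range in 5 of the 9 settings scored, among them quantile normalization (percentile 1.42), the loess specified before the data were examined (1.49) and the floor at the 25th percentile (0.38). Ccl3 (-1.17, level-adjusted -0.72) and Ccl4 (-0.89, from 6.68 to 5.79; level-adjusted -0.67), related chemokines, were the lowest members, and Ccl24 (0.40) and Ccl17 (0.095) the highest. NF-kappaB and proinflammatory cytokine genes had a median of -0.12 (18 of 26 lower, percentile 5.93). When level-adjusted, this median was -0.014, with 14 of 26 lower (percentile 23.7). Members ran from the inflammasome gene Nlrp3 (-0.53) and Rel (-0.51, level-adjusted -0.29) to Nfkb2 (0.31) and Icam1 (0.16, level-adjusted 0.31). Of 19 interferon-stimulated genes 13 were lower, with a median of -0.040 (percentile 10.98; 0.018 over the 7 genes compared with the floor at the 75th percentile), from Ifit3 (0.89) and Oas3 (0.32) to Ifitm3 (-0.51, level-adjusted -0.33) and Ddx58 (-0.21, a bound). MHC class I presentation genes were divided, 8 lower and 8 higher (median -0.033, percentile 77.5; level-adjusted 0.051, 10 of 16 higher), from the chaperone genes Calr (-0.64, level-adjusted -0.19) and Canx (-0.62, level-adjusted -0.20) to the proteasome activator gene Psme2 (0.51) and the peptide transporter gene Tap1 (0.22). Genes of alternative activation had a median of -0.12 (13 of 19 lower, percentile 7.43), with Clec7a (-0.41) and Tgm2 (-0.41) lowest and Ccl24 and Ccl17 highest. The lower values all but vanished when level-adjusted, with a median of 0.0078 and 12 of 19 higher. Clec7a was then at 0.044 and Tgm2 at 0.0078, against a spread of 0.33 for both. Immediate early genes had a median of -0.15 (19 of 27 lower, percentile 68.4), from Zfp36 (-0.85, level-adjusted -0.37) and Atf3 (-0.71, level-adjusted -0.24) to Ccn1 (0.22) and Dusp2 (0.21). Their direction turned with the scaling: the level-adjusted median was 0.094 with 17 of 27 higher (percentile 84.8), and the median after quantile normalization 0.097.

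Metabolic lists were near the random range, with fatty acid oxidation the exception on the deposited scale. Of its 23 compared genes 16 were lower, with a median of -0.11 (percentile 0.23), from Hadha (-0.56) and Etfb (-0.43) to Crat (0.10, level-adjusted 0.17) and Cpt2 (0.097). It was inside the range when level-adjusted (percentile 2.97) and with the floor at the 25th (8.44) or 75th percentile (32.8). Medians were -0.063 for complex I subunits (percentile 9.77), -0.076 for complexes II to V (25.6), -0.082 for the tricarboxylic acid cycle (4.74), -0.063 for glycolysis (6.75) and -0.017 for mitochondrial biogenesis and dynamics (32.5; level-adjusted median 0.011). Uqcrb (-0.75), Ndufb7 (-0.65), Mdh2 (-0.60) and Gapdh (-0.50) were the lowest members of the respiratory, tricarboxylic acid and glycolysis lists; Gapdh was at -0.031 when level-adjusted. Lipid uptake, storage and efflux genes had a median of -0.064 (21 of 33 lower, percentile 61.1). The level-adjusted median was -0.0058, with 17 of 33 lower (percentile 29.8). Lipa (-0.79) and the lipid droplet gene Plin2 (-0.66, level-adjusted -0.21) were lowest and Fabp4 (0.19) and Ppard (0.14) highest. Sterol biosynthesis (-0.052, percentile 14.6) and fatty acid synthesis (-0.079, percentile 6.26) were inside the range, with Pmvk (-0.31) and Scd1 (-0.51) lowest and Fdps (0.20) and Acacb (at least 0.21) highest. With the floor at the 75th percentile, 6 fatty acid synthesis genes were compared and lay below the range (median -0.28, percentile 2.01).

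Of the lists for RNA polymerase II transcription, the process in which Ssu72 acts, 2 had medians slightly below the range on the deposited scale, with calls that depended on the setting. Of 29 genes of mRNA cleavage, polyadenylation and C-terminal-domain phosphatases 21 were lower, with a median of -0.056 (percentile 1.27; level-adjusted -0.049, percentile 1.32). That call was lost with the floor at the 75th percentile (percentile 12.96) and without matching (5.245). The scaffold gene Sympk (-0.28) and Cpsf7 (-0.25) were lowest and Ctdsp1 (0.13, level-adjusted 0.20) and Cpsf1 (0.075) highest. RNA polymerase II, Mediator and elongation factor genes had a median of -0.072 (30 of 37 lower, percentile 2.42; level-adjusted percentile 2.74, inside the range, where it also lay in 4 other settings), from Ell2 (-0.63, level-adjusted -0.19) and Ccnk (-0.36) to Ctr9 (at least 0.16) and Ell (0.088). Integrator and snRNA processing genes (-0.025, percentile 16.7) and sister chromatid cohesion genes (-0.0051, percentile 42.3) lay inside the range. Of 34 cytosolic ribosomal protein genes 23 were lower, with a median of -0.27 (percentile 2.25), from Rps24 (-0.78, level-adjusted -0.51) and Rpsa (-0.68, level-adjusted -0.28) to Rps16 (0.35) and Rpl5 (0.31). That direction was lost with scaling, since the level-adjusted median was 0.0045 (percentile 34.7).

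Growth and stress lists lay inside the random range on the deposited scale at the floor chosen. Cell cycle genes had a median of 0.0023 (17 of 34 lower, percentile 48.1; -0.026 with the floor at the 75th percentile), with Pcna (-0.31) lowest and Foxm1 (0.20) highest. Medians were 0.010 for p53 targets (percentile 83.4; -0.11 with the floor at the 75th percentile), -0.049 for apoptosis regulators (8.61), -0.17 for NRF2 targets (17.3), -0.069 for heat shock genes (44.5; level-adjusted median 0.045) and -0.063 for autophagy genes (8.55). Gstp1, a glutathione transferase gene, was the highest NRF2 target (0.62), and Hspb1 (0.40) the highest heat shock gene. Unfolded protein and integrated stress response genes had a median of -0.11 (18 of 25 lower, percentile 10.1), with Atf3 (-0.71, level-adjusted -0.24) and the chaperone gene Hsp90b1 (-0.67, level-adjusted -0.22) lowest and Dnajc3 (0.36) highest. The list was below the range in 5 of the 9 settings scored: level-adjusted (percentile 1.40), with the loess over all features (1.37), after quantile normalization (1.12), with the floor at the 75th percentile (0.97) and without matching (0.20).

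Across the 50 lists fixed before the data were examined, 48 had at least 5 compared members and were scored. None lay above the central 95% of random lists, 12 lay below it and 36 inside, where chance alone would put 1.2 on each side; the lists share members, and genes of a list vary together. Replication-dependent histones, with 2 compared members (H1f2 at -0.0031, a bound, and H2bc3 at 0.088), and sex-linked genes, with 4, were not scored. When level-adjusted, none lay above and 9 below, 8 of them also below on the deposited scale. Without matching, 19 lay below, among them 7 that lay inside in every other setting: alveolar macrophage identity, complexes II to V, tricarboxylic acid cycle, NF-kappaB, alternative activation, NRF2 and immediate early genes.

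**Figure D3:**
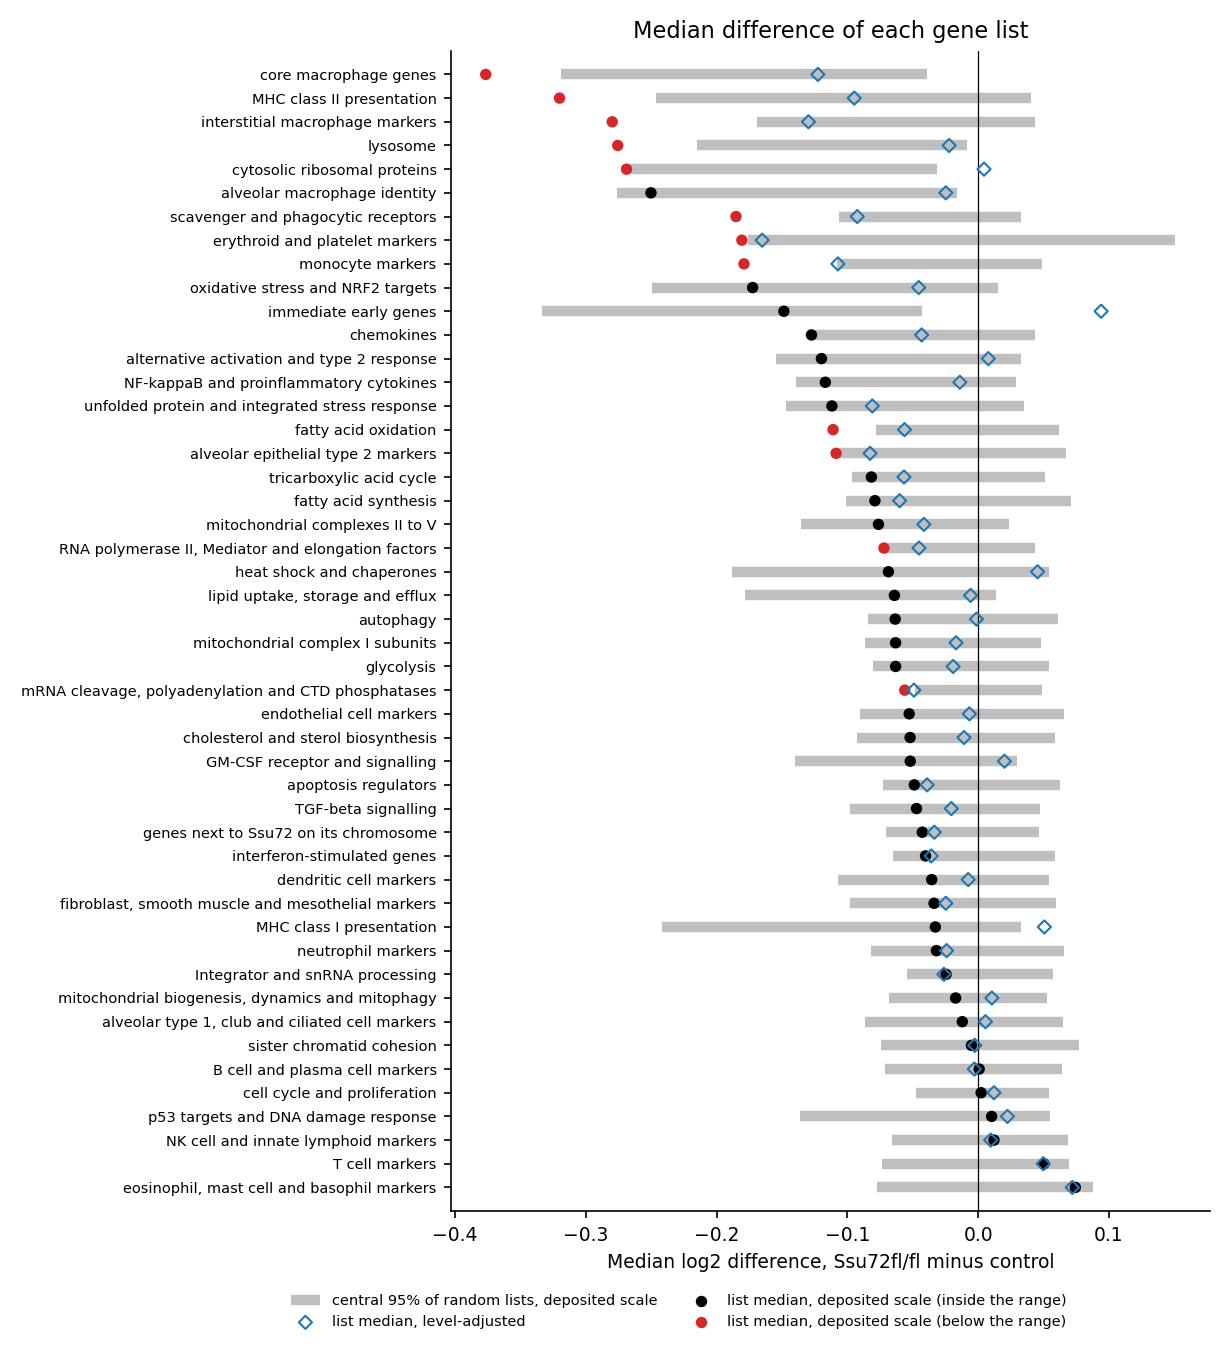
Median log2 difference (array labelled Ssu72fl/fl minus control) of the 48 scored gene lists on the deposited scale (filled circles, red for the 12 below the range) with the central 95% of random lists of matched signal on that scale (grey bars), and the level-adjusted medians (open diamonds, whose own random ranges are not drawn). On the deposited scale core macrophage genes have the lowest median, at -0.38; their level-adjusted median is -0.12, and the lowest level-adjusted one is -0.17, of the 5 erythroid and platelet markers.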

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

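The refitted loess and the count of protein-coding genes alone were chosen after seeing the data; the other alternatives were set before. The counts of 2-fold genes depended on scaling and threshold. Against 4 higher and 11 lower, there were 13 and 1 after quantile normalization, 11 and 1 with the loess over all features and with its refit, 41 and 178 at 1.5-fold, 1 and 0 at 3-fold, and 1 and 4 among protein-coding genes alone. Removing the level trend by construction lowers the count of lower genes, which lie at levels where most features are lower; which scaling is closer to the cells was not tested. Under the other alternatives 4 were higher and 10 to 12 lower. Probe set agreement became 0% of 1 gene after quantile normalization, where the cause was not tested, and had no value at 3-fold or with either loess because no gene past the threshold had a further compared probe set. The Ssu72 difference stayed above 0 in each setting. Lists above the random range numbered 1 (T cell markers, percentile 98.5) with the floor at the 75th percentile, which leaves 6545 genes, and 0 otherwise. Lists below it numbered 19 without matching, where the level trend enters by construction, and 9 to 12 otherwise. Across all 9 settings with list scores, the core macrophage, scavenger receptor, interstitial macrophage and monocyte lists lay below the range in each, MHC class II in 8, cleavage and polyadenylation in 7, alveolar type 2 in 6, chemokines, lysosome and the unfolded protein response in 5 each, fatty acid oxidation, ribosomal proteins and RNA polymerase II in 4 each, and 9 further lists in 1 each. Of these, dendritic cell markers and fatty acid synthesis lay below with the floor at the 75th percentile. The others, below only without matching, were alveolar macrophage identity, complexes II to V, tricarboxylic acid cycle, NF-kappaB, alternative activation, NRF2 and immediate early lists. Erythroid and platelet markers lay below in 6 of 8. The median of cytosolic ribosomal proteins moved from -0.27 to 0.0045 with the refitted loess, by removal of the trend. In total, 9 of the 50 list medians changed sign with the refit, 7 with the loess over all features and 7 with quantile normalization; the others with the refit, all inside the random range, were immediate early, heat shock, MHC class I, GM-CSF, alternative activation, mitochondrial biogenesis, B cell, and alveolar type 1, club and ciliated cell lists. Of 228 named genes, 8 changed sign with the refit and 7 with quantile normalization. Leaving out probe sets marked for cross-hybridisation was not run, since the platform has no such names. No replicate could be left out with 1 array per genotype. Signal limits the rest: 5.27% of features had a mean level over 6, and low signals cannot show a loss.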

Other observations

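All tests in this part were chosen after the results they bear on had been seen, and the patterns were found and tested on the same 2 arrays. For some gene groups outside the fixed lists, values are given without a test against random lists. All 10 compared mRNAs encoded by the mitochondrial genome were lower, with a median of -0.42, from ND3 (-0.71) to COX1 (-0.19). Among the 76 features above level 10, the 9 of these mRNAs had a median of -0.39, against -0.062 for the 67 others, whose robust SD was 0.41. Of 75 small nucleolar RNAs, which guide modification of other RNAs, 74 were lower (median -0.37, level-adjusted -0.099). The 52 of them at levels 6 to 10 had a median of -0.43, against -0.34 for all features there, and they made up 11 of the 100 largest deposited differences and 0 of the 100 largest level-adjusted ones. MicroRNA genes had no common direction, with 83 lower and 89 higher (median 0.0093). They were 1.32% of compared genes and 11 of the 100 with the largest differences (15 when level-adjusted), from -1.14 to 1.30. Olfactory and vomeronasal receptor genes were 1.88% of genes and 7 of those 100 (12 when level-adjusted).

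Protein-coding genes were also ranked by the difference left once the level trend was removed. Any ranking has such ends, and without replicate arrays it cannot be told which of them would recur. A set chosen after the values were seen took the 15 highest and 15 lowest level-adjusted differences among 1477 protein-coding genes with a mean level over 5.5. Receptor, immunoglobulin and some other multigene families were left out by symbol, but members of further families remained, such as Fthl17b, Ifnl2 and Ifna15. Of these genes 5 were at least 2-fold higher and 0 at least 2-fold lower. The highest were Ifit3 (1.31), Fthl17b (1.16), Rab3c (1.15), the interferon gene Ifnl2 (1.15) and Ptms (1.12). Further down were Wrnip1 (0.95), Gsc (0.90), Ifna15 (0.90), Zfp747 (0.89) and the small nuclear ribonucleoprotein gene Snrpg (0.80). Apol9a (0.80), Gstp1 (0.79), Psmb1 (0.78), Pim2 (0.78) and Smagp (0.77) completed the higher end. The lowest were Rbm39 (-0.78) and Hnrnpm (-0.73), which encode RNA-binding proteins that act in splicing, Ly86 (-0.75), a partner of the receptor RP105, and Psenen (-0.74). Ccl3 (-0.72), the chemokine receptor-like gene Ccrl2 (-0.70), the prostaglandin-degrading enzyme gene Hpgd (-0.69), Fcgr3 (-0.67), Ccl4 (-0.67), the tetraspanin gene Cd53 (-0.63) and H2-Ab1 (-0.63) were also among them. Rab1a (-0.66), Ech1 (-0.64), Lgmn (-0.61) and Wnk1 (-0.61) completed the lower end. The spread of deposited differences at these levels was 0.23 to 0.33. Xist and the Y-linked genes Eif2s3y, Kdm5d and Uty were near or below the floor on both arrays (Xist at 4.37 and 4.34), so the arrays did not show the sex of the mice.

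The lower signal on the array labelled Ssu72fl/fl at mid and high levels reached beyond the listed macrophage genes. A loss confined to the listed genes is argued against by 622 protein-coding genes outside the macrophage lists at levels 6 to 10. Their median was -0.25 (robust SD between genes 0.32), and 471 of them were lower. The sorted cells were macrophages, so genes outside the lists may be macrophage transcripts too. A wider loss of macrophage transcripts therefore cannot be judged from these values. Genes inside the macrophage lists were lower still, 54 of 54 with a median of -0.39 (robust SD 0.19). The groups were not matched on level, and the median of all features ran from -0.28 at levels 6 to 7 to -0.47 at 8 to 9. A share of the difference particular to the listed genes therefore stays open. An array-wide technical difference, such as in labelling, scanning or normalization, is a candidate explanation: 557 features without a gene name at those levels had a median of -0.37, and all 52 small nucleolar RNAs there were lower. A lower yield of transcripts in cells of mice labelled Ssu72fl/fl was not tested and stays open, since genotype and array coincide.

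The 12 lists below the random range on the deposited scale included those of core macrophage genes, scavenger receptors, interstitial macrophages and monocytes. The level trend as the cause for all 12 is argued against, because 7 of them also lay below the range with both loess fits; it may account for the 4 that lay inside with both, fatty acid oxidation, lysosome, cytosolic ribosomal proteins and RNA polymerase II. A lower share of macrophages among the sorted cells cannot be told apart from lower expression: the alveolar macrophage identity list stayed inside the range (percentile 17.9), and of the 11 lists for other cell types, from lymphoid to structural, erythroid and platelet, 0 lay above it and 2 below, with T cell markers above it at the highest floor alone (98.5). Fewer interstitial macrophages or monocytes passing the sort may contribute. Their 29 compared markers outside the alveolar and core macrophage lists, with the H2 genes of MHC class II left out, were at percentile 0.010. These markers belong to the pattern itself, so the value does not separate fewer such cells from lower expression per cell, an effect of genotype that 1 array per group cannot test.

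Ssu72 was not lower on the array labelled Ssu72fl/fl, and no explanation was settled. A complete loss down to the floor would have moved its probe set by -0.21, more than the spread of 0.14 at its level but of similar size. The array labelled Ssu72fl/fl read 4.998, above the floor of 4.65. Whether signal near the floor hid a loss therefore cannot be told. Probes outside the deleted part, swapped labels or incomplete recombination could each leave the observed 0.14, and the sources used here do not give the probe positions.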
